A study of Mus musculus with 8 samples.

How the data were processed

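Expression was profiled on Affymetrix mouse arrays, 1 per animal as far as the titles say, from bulge cells of back skin. Per the labels' protocols, DMBA (0.25 mg/ml) and TPA (0.02 mg/ml), 200 µl each in acetone, were applied weekly for 6 weeks from an age of 8 weeks, and the animals were 15 weeks old. Total RNA was extracted with TRizol, 25 ng were amplified by whole transcriptome amplification with 17 cycles, and 8 µg of cDNA were fragmented and biotinylated, per the labels' protocols. How the bulge cells were isolated, the sex of the animals, array batches and the deleted part of the gene are not given in the sources used here. The titles name an animal and a replicate number for each array, so limma and array permutation p-values were taken to measure the spread between animals. Camera with its preset correlation, Fisher's exact test and the neighbour shuffles compare genes with other genes, so their p-values do not measure that spread.

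The values are log2 expression per probe set that the authors made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set. The version and settings of RMA are not given in the sources used here. The deposited log2 values ran from 3.09 to 13.1, and array medians lay within 5.87 to 5.95, so no further normalization was applied. Values near the bottom of this range are mostly background, and RMA compresses differences there, so fold changes of dim genes are understated. Columns were assigned to samples through the labels, and 0 columns of other samples were present.

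Probe sets were named through the platform annotation: of 45141 probe sets, 28898 had 1 gene symbol, 551 had several and 15692 had none here, of which 104 were control probe sets. Those with several symbols were not named. The Entrez identifiers of 28689 were in the RefSeq gene table of GRCm38.p6, which left the symbols as they were and was otherwise used only for neighbours of genes. For each of 17097 genes the probe set with the highest mean over all 8 arrays was tested, and 7180 genes had more than 1.

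The 4 G9a cKO arrays were compared with the 4 G9a WT arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), two-sided, without covariates or a filter on dim probe sets. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05, over all genes tested. For the Ehmt2 probe sets, further probe sets of other genes and probe sets without a gene symbol they are over all probe sets. Single comparisons used exact permutation tests, for which 4 against 4 arrays allow no p below 0.0286. Errors are SD over animals, or the standard error of the limma fit where named. A simulated comparison over 17097 genes recovered 79.1% of genes seeded with a log2 change of 0.5, 97.0% of those with 1 and 100% of those with 2. Of its 194 called genes 10 (5.15%) were not seeded, and a list moved by 0.3 was found with 0 other lists called. Its noise was drawn independently for each gene, so it does not test for false list calls where members of a list vary together. In the real data the estimated correlation within a list reached 0.95, for the proliferation genes.

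These choices were fixed before the data were examined: the groups, the tests, 38 gene lists (22 of pathways and cell states and 16 of cell type and sex markers), the alternatives and the naming rule. The lists held 814 entries, of which 710 were measured, 2 of them under an older symbol. Lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation, and with fry. The rule names Ehmt2 and Ehmt1. It names the 10 largest rises and 10 largest falls among genes past the threshold whose cKO and WT values do not overlap, without unnamed gene models, of which 30 were past the threshold. It also names up to 4 members past the threshold per list, or those with the lowest p where none passed. Akr1c12 in the report, and the genes of the closing section that are outside this rule, were chosen after their values were seen.

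The alternatives were quantile normalization again, arrays shifted to a common median, dim probe sets left out (lowest 40%), the mean of all probe sets of a gene, eBayes without trend, array weights, the replicate number as a block, leaving out each array, other thresholds, and all probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.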

Results

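Gene expression was measured in bulge cells of mouse back skin that had been treated with DMBA, a mutagen, and TPA, a tumour promoter. The bulge is the part of the hair follicle that holds its stem cells. The treated cells came from 4 animals labelled G9a cKO, a conditional knockout of the histone methyltransferase G9a, and from 4 animals labelled G9a WT. The design text names a differential expression analysis of pre-neoplastic skin, so the question asked of the arrays was which transcripts differ with the G9a genotype before tumours form. Each array held 45141 probe sets, and the array medians lay between 5.87 and 5.95 on the log2 scale. Pearson correlations across genes were 0.996 to 0.998 between cKO arrays, 0.995 to 0.998 between WT arrays, and 0.994 to 0.997 between genotypes; genes are not independent replicates. No pair of arrays held identical values. The first principal component carried 37.3% of the variance and placed 8 of 8 arrays on the side of their genotype. WT replicate 4 lay nearest to the cKO arrays on it, at 2.92, while the other WT arrays lay between 10.6 and 12.7 and the cKO arrays between -12.2 and -5.95. The small number of arrays limits the precision of every value given here.

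Ehmt2, the gene that encodes G9a, was represented by 2 probe sets that gave different results. Probe set 1460692_PM_at read 5.85 ± 0.41 in cKO and 9.07 ± 0.19 in WT (log2, mean ± SD, n = 4 each), which is 9.27-fold lower in cKO and leaves 10.8% of the WT signal. Its log2 change was -3.21 (SE 0.18, limma adjusted p over all probe sets = 6.64e-05). The exact two-sided permutation test gave p = 0.0286, the smallest value that 4 against 4 arrays allow. The cKO arrays read 6.44, 5.54, 5.80 and 5.64, all below the lowest WT array at 8.89. Probe set 1426888_PM_at, the one with the higher mean over all arrays, read 8.41 ± 0.02 in cKO and 8.41 ± 0.01 in WT (limma adjusted p = 0.995; exact permutation p = 0.943, n = 4 each). Where the deleted part of the gene lies relative to either probe set is not given in the sources used here, and a probe set outside it checks nothing about the labels. Ehmt1, which encodes the partner methyltransferase GLP, read 9.18 ± 0.09 in cKO and 9.17 ± 0.07 in WT (limma adjusted p = 0.991).

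**Figure D1:**
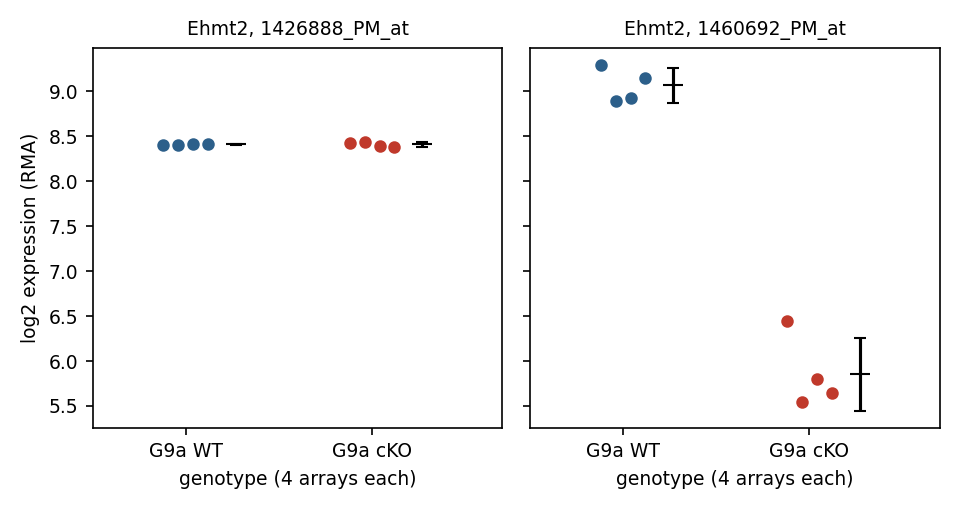
Log2 expression of the 2 Ehmt2 probe sets on each array (points), with the mean and SD of the 4 arrays per genotype (black bars). In 1460692_PM_at the highest cKO array reads 6.44 and the lowest WT array 8.89, while 1426888_PM_at lies at 8.41 in both genotypes.

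Across 17097 genes, 329 were higher and 143 lower in cKO than in WT at an adjusted p under 0.05. Among the 10 largest rises by the naming rule were those of an aldo-keto reductase (Akr1c13), a cell-surface antigen of intestinal epithelium (Gpa33), interferon-inducible tripartite-motif proteins (Trim30a, Trim30d) and a homologous recombination factor (Rad51b). By the same rule the 4 largest falls were in genes that encode a secreted protease inhibitor (Serpina3n), a hyaluronan synthase (Has2), a potassium channel (Kcnma1) and a beta-defensin (Defb6). Ehmt2 is not among the called genes, because its flat probe set was the one tested. Its log2 change of -3.21 in probe set 1460692_PM_at was a larger fall than any of these. Most differences were small: the median change was 1.39-fold among genes that rose and 1.34-fold among genes that fell, and 30 genes rose and 7 fell by at least 2-fold. Over all genes tested the median log2 change was 0.0027. The 4 cKO values and the 4 WT values did not overlap in 328 of the 329 genes that rose and in 142 of the 143 that fell. Over all genes the groups did not overlap in 8.24%, against 2.86% by chance for 4 against 4. The number of genes past the threshold depended on single arrays: it was 796 without WT replicate 4, and 258, 263, 293 and 304 without cKO replicate 2, WT replicate 3, cKO replicate 4 and WT replicate 1. A list of immediate early genes had a lower mean in cKO, and a fit with the mean of that list as a covariate, chosen after the data were seen, left 104 genes, 72 higher and 32 lower. Of the 49 genes past the threshold that belong to the fixed gene lists or to the 10 largest rises and falls, 30 did not pass it in that fit. The list mean itself differed between the genotypes, so that fit has less power, and a lost call need not be a lost change. Over all alternatives, that fit included, the log2 change stayed at 0.53 or above for Snrpn (main fit 0.67) and -0.82 or below for Hoxd9 (-0.99). It shrank to as little as -0.26 for Plk2 (-0.65) and -0.35 for Ptgs2 (-0.91).

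**Figure D2:**
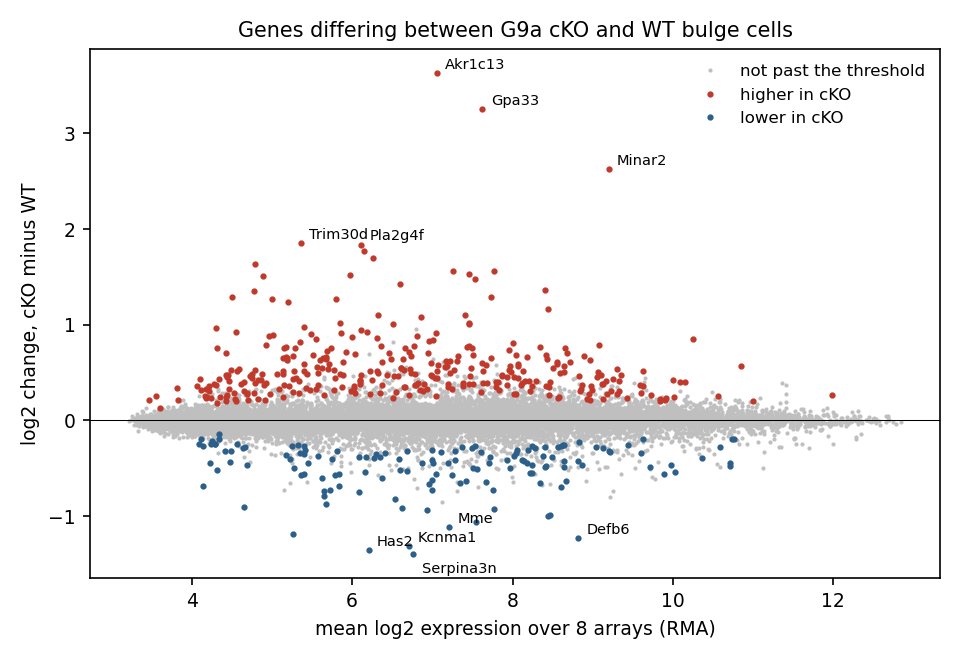
Log2 change (cKO minus WT) of each gene against its mean log2 expression over 8 arrays; red points are the 329 genes higher and blue points the 143 genes lower in cKO, and grey points did not pass the threshold. The 5 largest rises and 5 largest falls by the naming rule are labelled, and the rises reach further from 0 than the falls. Ehmt2 is plotted through its flat probe set, not through the one that fell.

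Among the 10 largest rises, Akr1c13 was 12.4-fold higher in cKO, at 8.87 ± 0.52 against 5.24 ± 0.29 (log2, mean ± SD, n = 4; limma adjusted p = 0.000167). Its close relative Akr1c12 also rose 2.12-fold, and the probe sets of such near-identical genes can share signal, so the part of each is uncertain. Gpa33 was 9.56-fold higher, at 9.25 ± 0.37 against 5.99 ± 0.43 (limma adjusted p = 0.000167). Minar2 was 6.17-fold higher, at 10.51 ± 0.32 against 7.89 ± 0.44 (limma adjusted p = 0.000396). Rad51b, a gene of recombination repair, was 3.25-fold higher, at 7.11 ± 0.22 against 5.41 ± 0.36 (limma adjusted p = 0.000756). Trim30d rose 3.61-fold and Trim30a 3.12-fold, and these neighbouring paralogs are uncertain in the same way as the Akr1c genes. The other 4 were Pla2g4f, a cytosolic phospholipase A, at 3.58-fold, Rimklb, an amino acid ligase, at 3.42-fold, and Efcab1 and Xkr6, both at 2.95-fold. All 10 kept an adjusted p under 0.05 in each of the 8 fits that left out 1 array and with the immediate early covariate. Of the further probe sets of these genes, 1 of Xkr6 and 2 dim ones of Rimklb did not pass the threshold.

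Among the 10 largest falls, Serpina3n was 2.63-fold lower in cKO, at 6.07 ± 0.15 against 7.46 ± 0.36 (log2, mean ± SD, n = 4; limma adjusted p = 0.00149). Has2 was 2.56-fold lower, at 5.53 ± 0.12 against 6.88 ± 0.31 (limma adjusted p = 0.000756). Kcnma1 was 2.49-fold lower, at 6.05 ± 0.35 against 7.37 ± 0.16 (limma adjusted p = 0.00193), while its dim second probe set did not pass the threshold. Defb6, on the list of basal and infundibular keratinocyte genes, was 2.35-fold lower, at 8.20 ± 0.13 against 9.43 ± 0.21 (limma adjusted p = 0.000439). Hpgd, the gene of a prostaglandin-degrading dehydrogenase, read 7.94 ± 0.05 against 8.94 ± 0.30 (limma adjusted p = 0.00215), and the homeobox gene Hoxd9 fell 1.99-fold and the membrane protein gene Tm4sf1 1.90-fold, without its dim further probe sets passing. Mme, which encodes the peptidase neprilysin, was 2.16-fold lower, the metalloproteinase gene Adamts1 2.09-fold and the transcriptional repressor gene Bhlhe40 1.92-fold. Mme and Bhlhe40 passed in 6 of the 8 fits without 1 array and Adamts1 in 3, with highest adjusted p of 0.0654, 0.0641 and 0.0852 by limma. Over these fits the log2 change ran from -1.23 to -0.97 for Mme, from -1.11 to -0.83 for Bhlhe40 and from -1.30 to -0.95 for Adamts1. With the immediate early covariate the change was -0.45 for Adamts1 (limma adjusted p = 0.288, alternatives from 0.000768 to 0.288). It was -0.43 for Bhlhe40 (limma adjusted p = 0.185, alternatives from 0.00186 to 0.185). Hoxd9 did not pass either (limma adjusted p = 0.0946), but its log2 change stayed at -0.82 or below in every alternative.

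**Figure D3:**
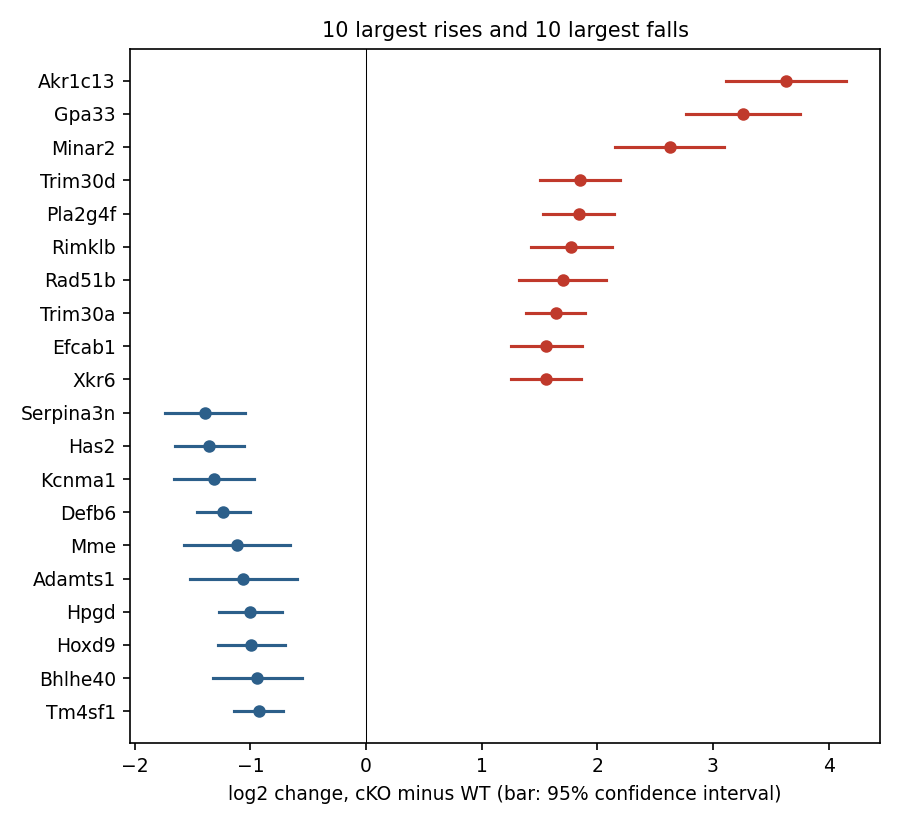
Log2 change (cKO minus WT) of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue) past the threshold, with 95% confidence intervals from limma as bars. Rises run from 1.56 for Xkr6 to 3.63 for Akr1c13 and falls from -0.93 for Tm4sf1 to -1.39 for Serpina3n. Ehmt2 is not among the falls, as it was tested through its flat probe set.

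The number of calls among genes of follicle stem cells and of epidermal fates was small. As a share of each list it was above that of all genes (472 of 17097 called), which was not tested. Of 26 measured bulge stem cell genes none rose and 2 fell: Fst, which encodes the activin and BMP antagonist follistatin (1.36-fold, limma adjusted p = 0.0154), and Foxc1, a transcription factor of bulge quiescence (1.22-fold, limma adjusted p = 0.0165). Adjusted over the list alone, 3 rose and 5 fell, and the list did not shift as a set (camera adjusted p = 0.356). Fst passed in 5 and Foxc1 in 4 of the 8 fits without 1 array, and without WT replicate 4 the list had 1 rise and 3 falls. Over all alternatives, the immediate early covariate included, the log2 change of Fst shrank from -0.44 to as little as -0.22. Of 25 genes of the hair shaft and inner root sheath, 3 rose and none fell, namely the homeobox genes Dlx3 (1.43-fold) and Msx2 (1.17-fold) and the inner root sheath keratin gene Krt71 (1.29-fold); 4 rose adjusted over the list alone. Msx2 passed in 1 and Krt71 in 4 of those 8 fits, 2 members rose without WT replicate 4, and the set did not shift (camera adjusted p = 0.356). Of 32 terminal differentiation genes, Sbsn rose (1.20-fold) and Krtdap fell (1.55-fold), both also adjusted over the list alone; without WT replicate 4, 5 rose and 1 fell. Of 18 stress keratin and alarmin genes, the serpin gene Serpinb3a (2.14-fold) and the matrix gene Tnc (1.19-fold) rose, the same count adjusted over the list alone. Neither of these lists shifted (camera adjusted p = 0.678 and 0.962).

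Targets of p53 lay mostly lower in cKO, and 2 DNA repair genes rose. Of 27 measured p53 targets, 3 fell and none rose. They were Plk2, a polo-like kinase (1.57-fold, limma adjusted p = 0.0432), Eda2r, a receptor (1.26-fold, 0.0228), and Mdm2, the p53 ubiquitin ligase (1.25-fold, 0.0265). Adjusted over the list alone, 5 fell, and 20 of the 27 lay below 0 (median log2 change -0.10, camera adjusted p = 0.00187; adjusted p = 0.593 with an estimated correlation). Eda2r passed in 4 of the 8 fits without 1 array, and Mdm2 and Plk2 in 2, while 5 members fell without WT replicate 4. Over all alternatives, the immediate early covariate included, the log2 change of Plk2 shrank to as little as -0.26. The list mean was low in cKO replicates 3 and 4 (-0.17 and -0.14). In cKO replicates 1 and 2 it was 0.030 and 0.028, close to the WT arrays at 0.038 to 0.072. With the immediate early covariate the set was not past the threshold (adjusted p = 0.101, where the alternatives ran from 9.04e-05 to 0.101). Of 29 genes of double-strand break repair and checkpoints, Rad51b (3.25-fold) and the end-joining factor gene Xrcc4 (1.38-fold, limma adjusted p = 0.00909) rose and none fell, also adjusted over the list alone; the set did not shift (camera adjusted p = 0.335). It was called higher without cKO replicate 3 and without WT replicate 4, and its alternatives ran from 0.0154 to 0.867. None of 34 proliferation genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.406). The lowest limma p was that of Rrm2, a ribonucleotide reductase subunit gene, at 9.15 ± 0.28 in cKO and 9.46 ± 0.14 in WT (adjusted p = 0.296). The proliferation list varied between animals of both genotypes, with mean deviations from -0.35 in cKO replicate 3 to 0.49 in WT replicate 4. Its set result depended on them: it was called lower without cKO replicate 1, without WT replicate 2 and with the immediate early covariate, while its median was 0.14 without WT replicate 4. The adjusted p of these alternatives ran from 0.000555 to 0.916.

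Interferon response genes lay mostly higher in cKO. Of 30 measured, 3 rose and none fell: Trim30a (3.12-fold), Ifit1 (1.43-fold, limma adjusted p = 0.00711) and Herc6 (1.30-fold, limma adjusted p = 0.0299), all interferon-induced. Adjusted over the list alone 7 rose, and 21 of 30 lay above 0 (median log2 change 0.093, camera adjusted p = 0.00134; adjusted p = 0.593 with an estimated correlation). Herc6 passed in 3 of the 8 fits without 1 array, and WT replicate 4 had the lowest list mean, at -0.23. Inflammatory cytokine and chemokine genes lay mostly lower. Of 25 measured, 1 fell, the prostaglandin synthase gene Ptgs2 (1.88-fold, limma adjusted p = 0.0471), which passed in 1 of those 8 fits. Over all alternatives, the immediate early covariate included, its log2 change shrank from -0.91 to as little as -0.35. Without WT replicate 4, 4 members fell. Adjusted over the list alone 1 rose and 4 fell, and 22 of 25 lay below 0 (median -0.11, camera adjusted p = 0.000426; adjusted p = 0.593 with an estimated correlation). Macrophage and monocyte markers also lay mostly lower, 14 of 17 of them below 0 (median -0.077, camera adjusted p = 0.0170; adjusted p = 0.843 with an estimated correlation). None of 16 antigen presentation genes passed over all genes and 1 fell adjusted over the list alone or without WT replicate 4 (camera adjusted p = 0.670).

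Immediate early genes, which respond within minutes to growth factors and to tissue dissociation, lay lower in cKO as a list without any single gene passing over all genes by the probe set tested; without WT replicate 4, 14 genes fell. All 20 measured lay below 0 (median log2 change -0.25), and 12 fell adjusted over the list alone. Egr2 read 9.47 ± 0.28 in cKO and 10.09 ± 0.25 in WT (log2, mean ± SD, n = 4; limma adjusted p = 0.0609), while its second probe set fell 1.64-fold (limma adjusted p over all probe sets = 0.0395), and Ier2 read 8.10 ± 0.10 and 8.52 ± 0.23 (limma adjusted p = 0.0746). The set was shifted with the preset correlation (camera adjusted p = 7.29e-11; adjusted p = 0.593 with an estimated correlation). The mean log2 change of the list was -0.30, and the exact permutation test of its 8 array means gave p = 0.0857, where the smallest possible is 0.0286. WT replicate 4 stood at -0.16, among the cKO arrays at -0.24 to -0.03, while the other WT arrays stood at 0.17 or above. Of 21 genes of RAS-ERK feedback and EGFR ligands none passed over all genes and 3 fell adjusted over the list alone; without WT replicate 4, 7 fell. Ier3 read 10.34 ± 0.12 in cKO and 10.83 ± 0.29 in WT (limma adjusted p = 0.0754) and Fosl1 8.00 ± 0.16 and 8.56 ± 0.34 (limma adjusted p = 0.0909). The set shift had a camera adjusted p of 0.00812 (adjusted p = 0.593 with an estimated correlation), and WT replicate 4 had the lowest list mean of all arrays, at -0.12. With the immediate early mean as a covariate, none of the immediate early, RAS-ERK and inflammatory lists was past the threshold, and the direction of each test, which is set against all other genes, turned. The median log2 change crossed 0 in the immediate early list (0.0073) but stayed at -0.027 in the RAS-ERK and -0.00080 in the inflammatory list. The camera adjusted p was 0.807 for the immediate early list, where its alternatives ran from 1.15e-20 to 0.807. For this list the outcome was fixed in advance, as the covariate is its own mean.

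Matrix and hypoxia genes lay mostly lower in cKO. Of 27 genes of mesenchymal transition and matrix remodelling, the collagen gene Col1a1 (1.88-fold, limma adjusted p = 0.00100) and the cadherin gene Cdh11 (1.61-fold, limma adjusted p = 0.00241) fell and none rose; adjusted over the list alone, 1 rose and 4 fell, and without WT replicate 4, 3 fell. The set had a median log2 change of -0.038 (camera adjusted p = 0.0146; adjusted p = 0.593 with an estimated correlation). Its shift was not past the threshold when dim probe sets were left out, nor with the immediate early covariate. Cdh11 lay near the bottom of the scale, at 3.80 ± 0.02 in cKO and 4.49 ± 0.22 in WT. Of 19 hypoxia and glycolysis genes, the carbonic anhydrase gene Car9 (1.36-fold, limma adjusted p = 0.0418) and the glycolytic kinase gene Pgk1 (1.14-fold, limma adjusted p = 0.0446) fell, and 5 fell adjusted over the list alone. The set had a median of -0.067 (camera adjusted p = 0.00185, or camera adjusted p = 0.593 with an estimated correlation). Its list mean was low in cKO replicates 3 and 4 (both -0.13). In cKO replicates 1 and 2 it was 0.020 and -0.034, against 0.018 to 0.15 in the WT arrays. Car9 and Pgk1 each passed in 1 of the 8 fits without 1 array, and 1 member fell without WT replicate 4. With the immediate early covariate the set was not past the threshold (adjusted p = 0.0804, where the alternatives ran from 0.000532 to 0.0804).

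The number of calls among chromatin genes and genes often silenced by repressive chromatin was small. The germline and imprinted lists held a larger share of calls than all genes (472 of 17097 called), which was not tested. None of 21 genes of the H3K9 methylation machinery passed over all genes or adjusted over the list alone (camera adjusted p = 0.525), with Ehmt2 entered through the flat probe set. The lowest limma p were those of Dnmt3b, a DNA methyltransferase gene, at 5.23 ± 0.09 in cKO and 5.39 ± 0.12 in WT (adjusted p = 0.326), and Kdm4a, a demethylase gene (adjusted p = 0.352). Of 32 germline and testis genes, the X-linked homeobox gene Rhox5 rose (1.28-fold, limma adjusted p = 0.0203) and the Piwi gene Piwil2 fell (1.25-fold, limma adjusted p = 0.0281), also adjusted over the list alone; both passed in 4 of the 8 fits without 1 array. Of 24 imprinted genes, Snrpn (1.60-fold, limma adjusted p = 0.00241) and Ndn (2.55-fold, limma adjusted p = 0.0493), both expressed from the paternal allele, rose and none fell. Adjusted over the list alone 3 rose and 3 fell, and without WT replicate 4, 3 rose and 2 fell. Ndn varied between cKO animals, at 5.45 ± 0.78 against 4.10 ± 0.22, and passed in 2 of those 8 fits. Neither list shifted (camera adjusted p = 0.439 and 0.678). For imprinted genes the mean log2 change was 0.027, opposite in sign to the median of -0.016 and to the test.

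Among metabolic and signalling lists, 24 xenobiotic and NRF2 genes included 2 that rose, Cyp1b1, which oxidises DMBA (1.46-fold, limma adjusted p = 0.0106), and the malic enzyme gene Me1 (1.38-fold, limma adjusted p = 0.0133); adjusted over the list alone 5 rose and 1 fell, and without WT replicate 4, 4 rose and 3 fell. Of 20 cholesterol and lipid synthesis genes the desaturase gene Fads1 rose (1.42-fold, limma adjusted p = 0.00845), the same count adjusted over the list alone. Of 18 circadian clock genes Bhlhe40 fell (1.92-fold), the same count adjusted over the list alone. Of 26 WNT, BMP and TGF-beta targets none passed over all genes, adjusted over the list alone 1 rose and 1 fell, and without WT replicate 4, 1 fell. Id3, a BMP target, read 10.24 ± 0.11 in cKO and 10.52 ± 0.09 in WT (limma adjusted p = 0.0527). These 4 lists did not shift (camera adjusted p = 0.904, 0.744, 0.356 and 0.671). Of 26 ribosomal protein genes none passed, also adjusted over the list alone, and the set had a median of -0.028 (camera adjusted p = 0.0480; adjusted p = 0.890 with an estimated correlation), a call that held in 7 of 16 alternative fits. Median, mean and test also differed in sign for the xenobiotic and stress keratin lists and for T cell, neutrophil and erythrocyte markers.

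Markers of other cells gave few calls, where 472 of 17097 genes passed over all. Of 11 interfollicular basal and infundibular keratinocyte genes, Defb6 (2.35-fold) and Ly6d (1.30-fold, limma adjusted p = 0.0218) fell and 3 fell adjusted over the list alone (camera adjusted p = 0.0851), and 3 fell over all genes without WT replicate 4; Ly6d passed in 5 of the 8 fits without 1 array. Of 16 fibroblast and dermal papilla markers Col1a1 fell, and of 12 T cell markers Thy1 rose (1.48-fold, limma adjusted p = 0.0251), each also adjusted over the list alone. Thy1 passed in 3 of those 8 fits. None of 17 macrophage and monocyte markers passed in either way, 1 fell without WT replicate 4, and the set had a median of -0.077 (camera adjusted p = 0.0170; adjusted p = 0.843 with an estimated correlation). Its lowest limma p was that of Cd68, at 5.07 ± 0.12 in cKO and 5.31 ± 0.12 in WT (adjusted p = 0.165), and the shift was not past the threshold without cKO replicate 3, WT replicate 2 or WT replicate 3, nor with the immediate early covariate, where its alternatives ran from 0.00140 to 0.996. No gene passed over all genes among markers of sebocytes (11 measured), Langerhans and dendritic cells (10), neutrophils (12), mast cells (9), melanocytes (14), endothelium (14), smooth and skeletal muscle and pericytes (12), Schwann cells and nerve (6), adipocytes (7), erythrocytes (5) and the hematopoietic lineage (10). Adjusted over each list alone, 1 Schwann cell gene, Egr2, fell and the other 10 lists had none, and the camera adjusted p of these lists was 0.162 or higher. Without WT replicate 4, 1 sebocyte gene rose and 1 Schwann cell gene fell over all genes. The 4 measured sex-linked genes were too few for a set test, and 1 rose adjusted over the list alone or without WT replicate 4. Xist read 5.20 ± 0.06 in cKO and 5.13 ± 0.12 in WT, and the Y-linked Kdm5d 8.35 ± 0.07 and 8.13 ± 0.12 (limma adjusted p = 0.731 and 0.153).

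Of 37 lists tested, camera with its preset correlation called 9, with 1 higher and 8 lower in cKO. With a correlation estimated from the data it called 0 (smallest adjusted p = 0.593), and 0 lists had an unadjusted p under 0.05. By fry, whose directional p asks whether the genes of a list move one way on balance, 1 list passed. This was the basal and infundibular keratinocyte list (fry adjusted p = 0.0169), and 7 lists had an unadjusted directional p under 0.05. Fry's mixed p, which counts changes in either direction, passed for further lists, the bulge and hair shaft lists among them. For others, such as proliferation, it did not. Some lists that camera did not call were called in alternatives: the basal and infundibular list with the replicate block, without cKO replicate 4 and without WT replicate 4, the melanocyte list with the mean of probe sets and without WT replicate 3, and the terminal differentiation and antigen presentation lists with the immediate early covariate. Further probe sets of the list members that rose or fell were adjusted over all probe sets. Of these, 1 did not pass for Fst, Foxc1, Dlx3, Msx2, Mdm2, Xrcc4, Ptgs2, Pgk1, Fads1, Serpinb3a, Tnc and Cyp1b1. It kept the sign in all of these but Cyp1b1. Adjusted in this way, the tested probe sets of Msx2, Ptgs2 and Pgk1 did not pass either (limma adjusted p = 0.0701, 0.0582 and 0.0600). Another further probe set passed for Serpinb3a (2.26-fold, limma adjusted p = 0.0115) and Cyp1b1 (1.53-fold, limma adjusted p = 0.00975).

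**Figure D4:**
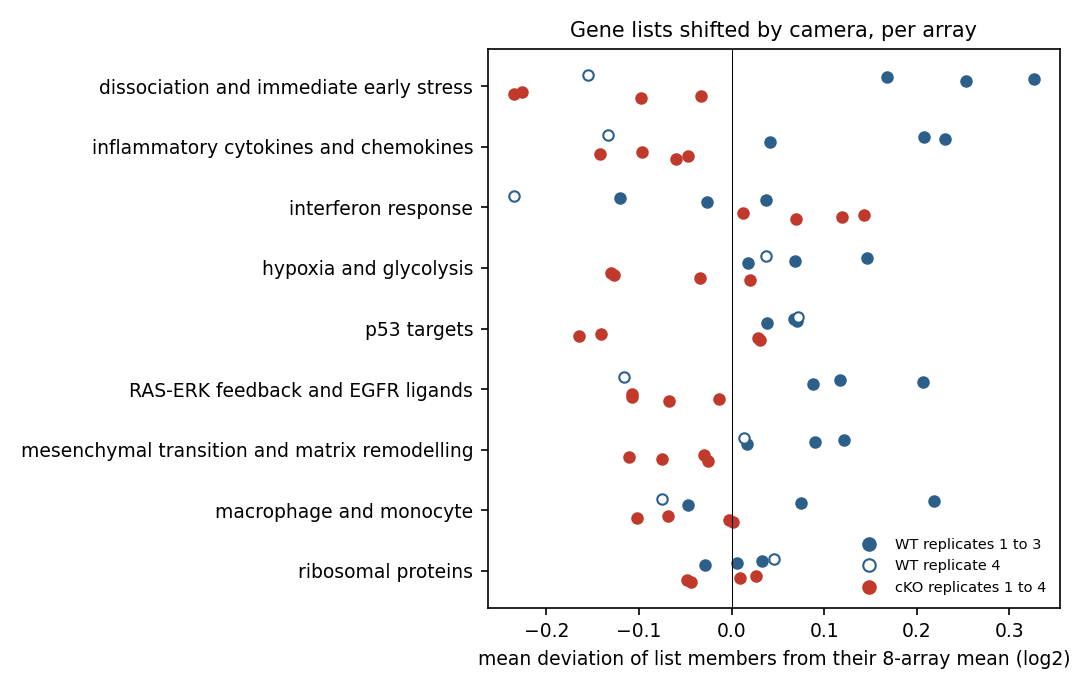
Mean deviation (log2) of the members of each list from their mean over 8 arrays, for the 9 lists that camera called with its preset correlation; each point is 1 array, red for cKO, blue for WT and open for WT replicate 4. In the immediate early, inflammatory and RAS-ERK lists WT replicate 4, at -0.16, -0.13 and -0.12, lies among or below the cKO arrays.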

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

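The tests of other splits of the arrays and of normalization were set before their outcomes were seen; the tests of second probe sets, flanking genes, handling, RNA degradation, other cells, genotype labels and the flat probe set were chosen after the results were seen.

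Of 202 sets of 4 arrays, one genotype of a named gene or list at a time, 15 held an array far from the other 3, where 10.1 would be flagged by chance. WT replicate 4 was the array in 6 of them: it was lowest in Adamts1 (7.37), Bhlhe40 (6.90), Fst (10.66), Ier2 (8.17) and Epb42 (6.01) and highest in Rad51b (5.95). In each of these 6 genes it was the WT array nearest to the cKO mean. In cKO, replicate 2 was highest in Akr1c13 (9.65), replicate 3 highest in Hpgd (8.02), replicate 4 lowest in Id3 (10.07) and Flt3 (4.73), and replicate 1 highest in Kdr (4.83). In WT, replicate 3 was highest in Skil (9.36) and Cd53 (4.62), replicate 2 highest in Slc36a2 (4.82), and replicate 1 lowest in the mean deviation of the p53 targets (0.038).

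Among 15588 probe sets without a gene symbol here, which the comparison of genes did not use, 126 were higher and 92 lower in cKO at a limma adjusted p under 0.05. The probe sets 1435382_PM_at (7.00-fold) and 1435383_PM_x_at (6.27-fold) rose most, and 1433601_PM_at (3.27-fold) and 1447174_PM_at (2.43-fold) fell most.

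The first pattern weighed is the set of 472 genes that differed, 69.7% of them higher in cKO. Chance is argued against but not excluded. Of the 35 splits of the arrays only 1, the real one, gave as many genes, and the highest of the others gave 59. The smallest share that 35 splits can give is 2.86%. Splits that mix the genotypes also have a wider spread within their groups if the genotypes differ, which lowers their counts. The share of higher genes was at least 68.9% under both other normalizations. The deposited values were already normalized by RMA, so these could change little and cannot show a distortion made before deposit. Of the 209 called genes with a second probe set, 93.3% moved the same way there (95% interval 89.0% to 96.3%). For those genes this argues against DNA variants under single probe sets, though 74 of the 209 passed the threshold there. DNA from the targeted strain next to Ehmt2 could account for few of the called genes. Of these, 1.27% lay among the 100 tested genes on either side (95% interval 0.468% to 2.75%). This check covers only that stretch, and strain DNA elsewhere in the genome was not tested. The G9a genotype stays open as a hypothesis, as does any difference between the 2 groups of animals, such as litter or isolation day, that the labels do not give.

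The second pattern is the lower immediate early list in cKO. RNA degradation stays open. The 3 prime minus 5 prime differences separated the genotypes in 0 of 3 control transcripts, but full separation of all arrays is a strict demand. They ran from -0.10 to -0.07 in cKO and -0.08 to -0.05 in WT for Gapdh, and from -0.36 to -0.28 and -0.32 to -0.24 for actin. For pyruvate carboxylase they ran from 0.67 to 0.85 in cKO and 0.52 to 0.77 in WT. The RNA had also been amplified, so these controls need not follow degradation. A lower share of immune, fibroblast or endothelial cells stays open: the 13 of their 68 measured markers above the array median had a median log2 change of 0.024 (95% interval -0.017 to 0.12) against -0.25 for the immediate early genes, but a high baseline would hide a small share in them, and the dimmer macrophage list had 14 of 17 markers below 0 (median -0.077). The most abundant of the 13 were Postn (11.83 in WT), Col6a1 (11.34) and Fbln1 (10.99); Postn is also on the bulge list and Col1a1 on the matrix list. Handling of single animals during cell isolation may be the source and cannot be told apart from the genotype, because the range within WT was 1.63 times the genotype difference, too wide to exclude it and too narrow to need it.

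The third pattern is the disagreement of the 2 Ehmt2 probe sets. Wrong genotype labels are argued against by a log2 gap of 2.45 between the lowest WT and the highest cKO array in the responding probe set. The flat probe set may lie outside the deleted part or may not follow the RNA. These cannot be told apart here, as it varied less over the 8 arrays than nearly all probe sets of similar level (0.0203% varied as little) and the position of the deletion is not used here.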

How the results depend on the processing

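All alternatives were planned except the immediate early covariate, which was chosen after the data were seen. Of the 49 named genes past the threshold, 28 kept an adjusted p under 0.05 in all 8 fits that left out 1 array. All 49 kept their direction there, which was fixed in advance, as their cKO and WT values do not overlap. Leaving out 1 array moved the genes past the threshold between 258 (without cKO replicate 2) and 796 (without WT replicate 4), those higher between 190 and 502 and those lower between 67 (without WT replicate 3) and 294. The count was also 263 without WT replicate 3, 293 without cKO replicate 4 and 304 without WT replicate 1; without WT replicate 4, 444 of the 472 genes were shared. Lists called ranged from 8 to 10, and 6 (without cKO replicate 3) to 7 of 7 arrays lay on their genotype's side of the first component. Array weights gave 732 genes, 249 of them lower. All probe sets gave 799, with 534 higher and 265 lower, as more features were counted. The adjusted p threshold of 0.1 gave 744 (497 and 247), and a minimum of 1.5-fold gave 141 (108 and 33). The covariate gave 104 genes (72 and 32), without 30 of the 49 named genes. Some of these 30 kept most of their log2 change, such as Snrpn at 0.53 or above in every alternative (main fit 0.67). Others did not, such as Plk2 at as little as -0.26 (main fit -0.65). With the covariate 5 lists were called. The median log2 changes were -0.027 for RAS-ERK, -0.00080 for inflammatory and 0.0073 for immediate early genes, and the tests of these lists turned direction against other genes. For the immediate early list this follows from the covariate itself. With the replicate number as a block 268 genes were called (191 and 77), 256 of them shared. The numbers do not pair the arrays: residual correlations of same-numbered arrays were -0.33, -0.27, -0.53 and 0.03, and 0 arrays correlated best with their own number. Lists fell to 0 with an estimated correlation and to 1 by the directional p of fry. The other Ehmt2 probe set gave -3.21. Otherwise the cause was not tested. The other normalizations, the dim filter, the mean of probe sets and the fit without trend gave 486, 458, 388, 495 and 473 genes. Values near the bottom of the scale are limited by background.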

Other observations

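The gene families and the neighbour count given here were chosen after the results were seen, and the test of other splits for the number of gene lists was set before.

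Of 34 measured Hox genes, the homeobox genes of body position, 6 fell and none rose in cKO: Hoxd9 (1.99-fold), Hoxa5 (1.40-fold), Hoxb7 (1.38-fold), Hoxa3 (1.26-fold), Hoxb5 (1.20-fold) and Hoxb6 (1.20-fold). This was the family whose shift held with an estimated correlation (camera adjusted p = 0.0137 over 11 families). With the preset correlation the real split gave the smallest p of 35 splits for the Hox, Trim, Casp and Akr1 families alike. For the Bex, Armcx and Tceal genes 2 splits gave as small a p, and for the Zfp genes 3. As the families were chosen after these results were seen, neither this ranking nor the adjusted p over 11 families is independent support. Of 51 Trim genes 5 rose, Trim30d, Trim30a, Trim12c (1.47-fold), Trim34a (1.37-fold) and Trim12a (1.33-fold), and none fell (adjusted p = 0.0935 with an estimated correlation). Of 8 caspase genes the inflammatory caspase genes Casp1 (1.61-fold, limma adjusted p = 0.000627), Casp4 (1.35-fold) and Casp12 (1.18-fold) rose and none fell (adjusted p = 0.0846 with an estimated correlation). Of 28 complement genes C1s1 (2.24-fold), the complement inhibitor gene Serping1 (2.15-fold) and C1rb (1.57-fold) rose, while the family's median lay at -0.022 and it did not shift (camera adjusted p = 0.832). Of 16 Bex, Armcx and Tceal genes of the X chromosome 4 rose, Armcx2 (1.90-fold), Bex1 (1.69-fold), Bex2 (1.55-fold) and Armcx6 (1.30-fold), with none lower (adjusted p = 0.112 with an estimated correlation). Of 301 Zfp genes 15 rose and 1 fell (adjusted p = 0.112 with an estimated correlation), and without WT replicate 4, 27 rose and 2 fell. The Hox, Casp, complement and Bex counts were the same under both other normalizations, under which 6 and 5 Trim genes and 15 and 16 Zfp genes rose.

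Genes that differed tended to lie next to each other. Among 17055 tested genes with a place in the RefSeq gene table, 35 pairs of next neighbours were both called in the same direction and 3 in opposite directions. Shuffling the calls over the genes gave a mean of 7.42 same-direction pairs and at most 19 (permutation p = 1e-04, the smallest that 10000 shuffles can give). The pairs include Trim12a, Trim12c, Trim30a and Trim30d in a row, Casp1, Casp4 and Casp12 in a row, Hoxb5 to Hoxb7, C1s1 with C1rb, and Nat1 with Nat2, all but the Hox genes higher in cKO. In 15 of the 35 pairs the symbols share the letters before their first digit, a rule that misses related pairs such as Hoxaas2 with Hoxa3 and Snrpn with Snurf. Whether shared probe signal or overlapping transcripts add to the count was not tested, and shuffling takes no account of neighbours that vary together in any tissue. Of 597 genes on the X chromosome 21 rose and 5 fell, 4.36% against 2.70% of other genes (Fisher's exact test, adjusted p = 0.0294 over 11 families). They did not shift as a set (camera adjusted p = 0.461, and adjusted p = 0.776 with an estimated correlation), and 6 of 35 splits gave as small a camera p.

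Chance could not be excluded for the number of gene lists called. Of the 35 splits of the arrays, 5 gave as many as the 9 lists, the real one included. The highest of the others gave 13. Among the 9 lists, as small a camera p came from 2 splits for the matrix and hypoxia lists and 6 for the p53 and immediate early lists. It came from 7 for the interferon list, 8 for the inflammatory and RAS-ERK lists and 12 for the macrophage and ribosomal lists, the real split included. The lists with the largest ranges between arrays were proliferation, with a range of 0.84 and a genotype difference of -0.039, and the immediate early list, with a range of 0.56 and a difference of -0.30. For the proliferation list cKO replicate 1 (0.42) and WT replicate 4 (0.49) were highest.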
